A study of Homo sapiens with 12 samples.

How the data were processed

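Gene expression was measured by RNA sequencing in 12 libraries of U937 cells, 3 in each of 4 groups. Per the labels' protocols, total RNA was extracted with TRIzol and treated with DNase I, and libraries were made with an Illumina TruSeq RNA kit. Per the submitters' processing notes, reads were aligned with STAR to the hg19 genome build. The STAR version, the gene annotation and the sequencing layout are not given in the sources used here. The deposited files hold, per the file layout, raw read counts per gene as STAR writes them, with 1 file per library, 57820 genes, summary lines for reads not assigned to a gene, and 3 columns of counts for reads counted without strand and on either strand. The authors' counts were not normalised. The column without strand was used. The second strand column held 95.7% of the reads counted by strand, although the kit named in the labels is not one that marks strand, so this column was tried as an alternative. In the column used, reads of a gene and of an overlapping antisense gene cannot be told apart.

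Groups and replicate numbers were taken from the sample titles. Reads outside genes were left out of library sizes and tests. On average over the 12 libraries, 14.7% of reads were not aligned, 3.82% aligned to several places, 17.8% lay outside annotated genes and 4.26% were ambiguous between genes. Reads assigned to genes numbered 24989728 to 31310319 per library. Replicates of a group differed by more than counting noise (chi-square per degree of freedom 3.50 to 29.4 over genes with at least 20 reads in the pair), so no 2 files were treated as one library.

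Gene symbols came from an annotation of the GRCh38 build by Ensembl identifier, which gave a symbol for 52338 of 57820 genes. Because that build differs from the one used for alignment, it served only for names, gene types, the chromosome and order of genes, and the GC content and length of the longest transcript, and no coordinates are printed. GC content and length were known for 18046 of the 18689 genes tested (96.6%).

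Genes were filtered with filterByExpr by group, library sizes were scaled by TMM, and all 12 libraries were fitted together in edgeR 4.0.16 with the quasi-likelihood test (R 4.3.3, robust estimation off, no covariate), so that the groups shared 1 estimate of the spread. The 7 tests were each knockdown group against shControl, the 3 differences between knockdown groups and the interaction. Genes at a Benjamini-Hochberg adjusted p below 0.05 were called. SEs were computed from the fold change and the F statistic, and 95% intervals from those SEs. Of 36 gene lists fixed in advance, 35 had at least 4 measured genes and were tested with camera (preset correlation 0.01, Benjamini-Hochberg adjustment over the 35 lists in each comparison). They covered chromatin regulators, DNA repair, cell death, cell cycle, metabolism, stress, immune signalling, blood lineages and RNA quality. The list of fibroblast and epithelial markers had 3 measured genes and was not tested. With an estimated correlation, 0 lists passed in shKDM6A, 3 in shKDM6B and 0 in shKDM6A+6B.

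Genes named in the text are KDM6A and KDM6B, and for each knockdown against shControl the 8 largest rises and 8 largest falls among called protein-coding genes with a mean of at least 5 CPM over the 12 libraries and no overlap between the groups' libraries. From each list, up to 2 rising and 2 falling called genes with the smallest adjusted p could be named per comparison with shControl. For the other 4 tests it was the 3 largest rises and 3 largest falls. Where such a gene is followed into a further group, its values there are given for comparison. Genes on the Y chromosome and XIST were left out. Groups, tests, gene lists, naming rule and 13 alternatives were chosen before the data were examined. The alternatives were other scaling, filters, tests (DESeq2 1.42.0 and limma 3.58.1 voom), robust estimation, the strand column, the replicate number as a block, only the compared groups in the fit, a 2-fold minimum, other list tests and leaving out each library in turn. A correction for GC content and gene length was added after seeing the data: the trend of each library's log2 CPM on GC content and then on length was fitted by loess (span 0.5) and removed through offsets.

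The steps were tested on simulated data. For shKDM6A against shControl, counts of 17613 genes were drawn with 200 genes changed. The test recovered 32 of 67 genes changed by 0.5 on the log2 scale, 60 of 67 changed by 1 and 66 of 66 changed by 2, and 5 unchanged genes were called. With no gene changed, 1 gene was called. In the data 6647 genes were called in this comparison and libraries of a group differed along GC content, which these draws left out. The rates of recovery and false calls therefore need not hold there. A list shifted by 0.5 was found by camera with both forms of correlation, and 0 other lists were called. Genes were drawn independently of each other, so this does not test false list calls where genes of a list move together. For shKDM6A+6B against shControl, a simulated GC trend over 17732 genes gave 6250 calls of unchanged genes without the correction and 7 with it, while 130 and 127 of 133 genes changed by at least 1 were recovered.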

Results

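U937 is a human monocytic cell line. RNA sequencing was done on U937 cells with a control short hairpin RNA (shControl) and on 3 derivatives with hairpins against KDM6A (shKDM6A), KDM6B (shKDM6B) or both (shKDM6A+6B), with 3 libraries in each of the 4 groups. KDM6A (UTX) and KDM6B (JMJD3) are demethylases that remove methyl groups from the histone residue H3K27, whose trimethylation is a repressive mark. The labels number the replicates without saying that they were separate cultures, so p-values measure only the spread between these samples, which may be technical. Between 24989728 and 31310319 reads per library were assigned to genes. Reads without an alignment made up 13.9% ± 1.10 of the reads in shControl, 20.4% ± 1.87 in shKDM6A, 14.6% ± 0.936 in shKDM6B and 10.0% ± 0.415 in shKDM6A+6B (mean ± SD, n = 3 each). Levels below are mean counts-per-million (CPM) ± SD with n = 3 per group, and every adjusted p for a gene is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 18689 genes.

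KDM6A RNA was lower in both groups that carried a hairpin against it. It was at 86.3 ± 5.63 CPM in shControl, 58.3 ± 3.58 CPM in shKDM6A and 46.2 ± 3.64 CPM in shKDM6A+6B. The log2 fold change against shControl was -0.56 in shKDM6A (SE 0.08, adjusted p = 1.2e-04) and -0.90 in shKDM6A+6B (SE 0.08, adjusted p = 1.5e-06), and all 3 libraries of each group lay below all 3 control libraries. In the libraries labelled shKDM6B, KDM6A RNA was higher, at 107 ± 9.76 CPM (log2 fold change 0.31, SE 0.08, adjusted p = 0.0092). Without shControl replicate 2 that rise no longer passed the threshold (log2 fold change 0.28, adjusted p = 0.057).

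KDM6B RNA was low in every group, and no drop against shControl was called where the labels name a hairpin against it. It was at 1.74 ± 0.240 CPM in shControl, 1.79 ± 0.117 CPM in shKDM6A, 1.53 ± 0.137 CPM in the libraries labelled shKDM6B and 1.99 ± 0.452 CPM in the libraries labelled shKDM6A+6B. In the libraries labelled shKDM6B the log2 fold change was -0.19 (95% interval -0.61 to 0.23, edgeR adjusted p = 0.47), and in those labelled shKDM6A+6B it was 0.19 (95% interval -0.21 to 0.60, edgeR adjusted p = 0.41). With a correction for GC content and gene length the value in the latter was -0.44 (95% interval -0.85 to -0.03, adjusted p = 0.063). Against shKDM6A the corrected value in shKDM6A+6B was -0.55 (95% interval -0.97 to -0.14, edgeR adjusted p = 0.033), which passed. These intervals cover the spread of these libraries only. The groups are called by their labels below, and a difference in a group labelled shKDM6B or shKDM6A+6B is not shown to follow from less KDM6B RNA.

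**Figure D1:**
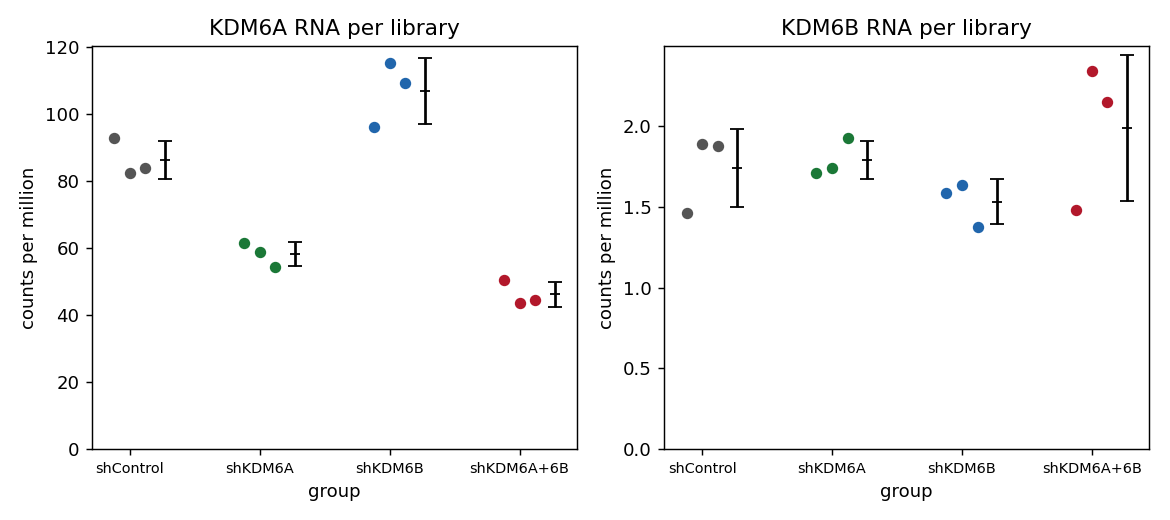
KDM6A and KDM6B RNA in CPM (vertical axis) for each library in the 4 groups (horizontal axis); points are libraries, and the black bar is the mean with its SD (n = 3). KDM6A averaged 58.3 in shKDM6A and 46.2 in shKDM6A+6B against 86.3 in shControl, while KDM6B averaged between 1.53 and 1.99 in all 4 groups.

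The comparison of shKDM6A with shControl addressed depletion of KDM6A, whose RNA was at 67.6% of its control level. It cannot tell that depletion apart from another difference between the lines. Genes of monocyte and macrophage maturation and type I interferon-stimulated genes rose as groups, while genes of class I antigen presentation and G2/M genes fell, by camera with a preset correlation. None of these 4 lists passed with an estimated correlation (adjusted p = 0.18, 0.18, 0.30 and 0.67). TLR2, a receptor for bacterial lipoproteins, rose from 3.98 ± 0.359 to 26.6 ± 1.77 CPM, and the chemokine receptor gene CCR2 rose from 1.68 ± 0.0854 to 9.60 ± 1.10 CPM. The interferon-induced gene XAF1 rose from 0.933 ± 0.106 to 11.5 ± 0.549 CPM, a 12.3-fold change. BCL2A1, an anti-apoptotic member of the BCL2 family, fell from 117 ± 9.20 to 21.1 ± 1.79 CPM, and CDC25C, a phosphatase acting at entry into mitosis, fell from 10.1 ± 1.44 to 0.241 ± 0.115 CPM. In all, 6647 genes changed at an adjusted p below 0.05, of which 3359 were higher and 3288 lower, and 2004 of them changed at least 2-fold.

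Among protein-coding genes with a mean of at least 5 CPM over the 12 libraries, the largest rises after XAF1 were those of GPR85 (log2 fold change 3.45, SE 0.19), RGS1, RNF175, NOG, CD109, AFDN and FBLN1, the last with 3.02 (SE 0.11). AFDN, which encodes an adaptor of cell junctions, went from 12.1 ± 0.943 to 98.5 ± 0.776 CPM. The largest falls were those of DNAJC15, CTPS2, GATM, TMEM170B, H3C4, UNC5C, MMP1 and NWD1, of which H3C4 is uncertain because histone genes share sequence. DNAJC15, a mitochondrial co-chaperone gene, went from 24.5 ± 3.76 to 0.0506 ± 0.0580 CPM, and CTPS2, which encodes a CTP synthase, from 25.8 ± 1.24 to 0.114 ± 0.113 CPM. GATM, which encodes an enzyme of creatine synthesis, went from 51.2 ± 2.66 to 0.836 ± 0.281 CPM. The adjusted p of these 16 genes was at most 1.7e-07 by edgeR's quasi-likelihood test. CDC25C, with a log2 fold change of -5.36 (SE 0.32), lay below that mean.

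Of the 36 measured genes of monocyte and macrophage maturation, 18 rose and 7 fell, with the same counts when adjusted over the list alone. Their median log2 fold change was 0.44 (camera with a preset correlation, adjusted p = 5.4e-06, and adjusted p = 0.18 with an estimated correlation). Among those that fell were CTSS (log2 fold change -0.38, SE 0.07) and FCN1 (-1.06, SE 0.20). Of 31 interferon-stimulated genes 19 rose and 4 fell, again 19 and 4 adjusted over the list alone, with a median of 0.68 (camera adjusted p = 1.1e-05, and adjusted p = 0.18 with an estimated correlation). IFI6 rose (1.71, SE 0.09), while USP18, which encodes a brake on interferon signalling, fell (-1.14, SE 0.13), as did MX2 (-0.45, SE 0.05). Of 17 class I genes 11 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.60 (camera adjusted p = 1.8e-04, and adjusted p = 0.30 with an estimated correlation). HLA-B fell from 324 ± 15.4 to 120 ± 9.95 CPM and HLA-C from 169 ± 13.96 to 71.2 ± 10.2 CPM, both uncertain because their reads can be shared with related HLA genes. The list's 10 genes in the first of 3 equal parts of chromosome 6 by gene order had a median of -0.62 after correction for GC content and gene length, and the other 185 measured genes of that part had -0.59. The 7 members elsewhere had a median of -0.07 (-1.35 to 0.25). Of 33 G2/M genes 15 fell and 2 rose (16 and 2 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.015, and adjusted p = 0.67 with an estimated correlation). This call was also lost with a stricter filter (adjusted p = 0.11) and with the strand column (adjusted p = 0.080). KIF23 (-0.64, SE 0.07) and KIF20A (-0.58, SE 0.05), kinesins of late mitosis, fell, and KIF2C rose (0.30, SE 0.05).

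No other list passed in shKDM6A without the GC and length correction, although single members changed. Of 28 stress response genes 13 rose and 1 fell over all genes and also adjusted over the list alone (camera adjusted p = 0.10, and 0.024 after the correction), with a median of 0.22. Of 23 cholesterol synthesis genes 5 rose and 2 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.21, and 0.043 after the correction), with a median of 0.12. With an estimated correlation, and without the GC and length correction, neither passed (adjusted p = 0.46 and 0.57). Among chromatin regulators, the H3K27 methyltransferase gene EZH2 rose (log2 fold change 0.65, SE 0.06), its partner JARID2 fell (-1.19, SE 0.06), and the demethylase genes KDM7A (1.37, SE 0.09) and KDM4A (0.71, SE 0.08) rose. Over the 25 Polycomb genes 5 rose and 7 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.51). Over the 16 genes of H3K27 demethylases and jumonji relatives 7 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.33). In the 15 primary granule genes, LYZ (0.99, SE 0.07) and SRGN (1.01, SE 0.07) rose and CST7 (-2.20, SE 0.08) and SERPINB1 (-1.21, SE 0.06) fell, 3 rising and 5 falling in all, with the same counts adjusted over the list alone (camera adjusted p = 0.35). Of 26 NF-kappaB and cytokine genes 11 rose and 6 fell over all genes and also adjusted over the list alone (camera adjusted p = 0.35). NFKBIZ (1.08, SE 0.08) and CXCL8 (0.91, SE 0.09) rose, and TNF (-2.47, SE 0.17) and CD83 (-0.83, SE 0.09) fell. Of 15 stem and progenitor genes 7 rose and 6 fell over all genes and also adjusted over the list alone (camera adjusted p = 0.38), with MEF2C higher (1.64, SE 0.12) and SOX4 lower (-1.82, SE 0.08). Single genes were not set against their neighbours on the chromosome. After the GC and length correction, 90.2% of 194 genes in the first of 3 parts of chromosome 6 were lower in shKDM6A. So were 94.2% of 104 genes of chromosome 21, but only 14.2% of 388 genes in the first part of chromosome 1. These parts moved in the same direction in the other 2 knockdown groups. Changes of single genes there were not separated from those of their segment. The same holds for other shifted chromosomes, such as 15, where 71.1% of 384 genes were lower in shKDM6A after that correction.

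In the repair lists FANCE (1.81, SE 0.15) and GTF2H3 (1.70, SE 0.07) rose in shKDM6A, while FANCD2 (-0.56, SE 0.06), the glycosylase gene OGG1 (-1.27, SE 0.13) and RNF168 (-0.88, SE 0.07) fell. The camera adjusted p was 0.49 for homologous recombination, 0.50 for end joining, 0.89 for the Fanconi anaemia pathway, 0.33 for base excision repair, 0.33 for nucleotide excision repair, 0.94 for mismatch repair and 0.36 for checkpoint signalling. It was 0.35 for HOX genes and cofactors, of which 5 rose and 1 fell (7 and 1 adjusted over the list alone), 0.10 for G1/S genes, 0.10 for nuclear-encoded oxidative phosphorylation, 0.21 for anti-apoptotic and 0.35 for pro-apoptotic BCL2 family genes, and 0.35 for replication-dependent histone genes. The median, mean and test of a list differed in sign for the H3K4 methyltransferase complexes (median 0.02, mean 0.0048, test lower) and for lymphocyte markers (median -0.17, mean 0.13, test higher), and neither passed. PDIA3 (0.26, SE 0.07, edgeR adjusted p = 0.011), the class I list's 1 rising gene, did not pass without shControl replicate 2 (adjusted p = 0.060) or replicate 3 (adjusted p = 0.062).

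The comparison of the libraries labelled shKDM6B with shControl addressed depletion of KDM6B, although no drop of KDM6B RNA was detected in them. Monocyte and macrophage genes and interferon-stimulated genes rose. S100A8, an alarmin gene of maturing myeloid cells, went from 4.83 ± 0.488 to 119 ± 5.63 CPM (24.7-fold), and S100A9, its partner, from 6.37 ± 0.659 to 105 ± 3.92 CPM (16.5-fold). LYZ, which encodes lysozyme, went from 695 ± 33.5 to 3917 ± 186 CPM. The interferon-induced genes XAF1 and IFIT3 rose 14.8-fold and 4.42-fold, and the cytokine gene CXCL8 rose 3.51-fold from 137 ± 5.96 to 482 ± 55.5 CPM. CDKN1A, a cell cycle inhibitor gene, rose from 4.98 ± 0.402 to 28.5 ± 2.91 CPM, while the proliferation marker gene MKI67 fell from 923 ± 56.2 to 481 ± 51.5 CPM. At an adjusted p below 0.05, 7383 genes changed, 3838 higher and 3545 lower, and 2258 of them changed at least 2-fold.

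With the same limit of 5 CPM over the 12 libraries, the largest rises were those of PPBP, ATP6V0D2, TDO2, F13A1, ABCA1, KYNU, ADAM28 and S100A8. PPBP, which encodes a platelet chemokine precursor, went from 0.291 ± 0.2004 to 26.7 ± 0.938 CPM (log2 fold change 6.51, SE 0.25), and TDO2, which encodes a tryptophan dioxygenase, from 4.76 ± 0.933 to 194 ± 18.03 CPM (5.36, SE 0.15). F13A1, the gene of coagulation factor XIII A, rose 37.4-fold, and the cholesterol exporter gene ABCA1 rose 33.6-fold. The largest falls were those of DNAJC15 (-8.12, SE 0.31), CTPS2 (-7.85, SE 0.40), GATM (-5.95, SE 0.28), SLC27A2, ARAP2, UNC5C, FPR2 and APLN (-2.62, SE 0.20). CDC25C, below that limit, fell more than several of them (-5.00, SE 0.30). By edgeR's quasi-likelihood test the adjusted p of these 16 genes was at most 2.0e-07.

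Of 36 monocyte and macrophage genes 31 rose and 1, EGR1 (-0.68, SE 0.15), fell, with the same counts adjusted over the list alone. Their median log2 fold change was 1.49 (camera adjusted p = 5.0e-42, and adjusted p = 4.1e-04 with an estimated correlation). Of 31 interferon-stimulated genes 24 rose and 1, MX2 (-0.38, SE 0.05), fell (25 and 2 adjusted over the list alone), with a median of 1.22 (camera adjusted p = 1.3e-20, and adjusted p = 0.0037 with an estimated correlation). Of 26 NF-kappaB and cytokine genes 17 rose and 3 fell (18 and 3 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 1.6e-07, and adjusted p = 0.030 with an estimated correlation). SOD2 rose (1.19, SE 0.06), whereas TNF (-2.09, SE 0.16) and CD83 (-0.58, SE 0.09) fell. These 3 lists passed with both forms of the test. Their falling members were not set against their neighbours on the chromosome. Of 104 measured chromosome 21 genes, 86.5% were lower in this group after the GC and length correction (median -0.43).

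Another 8 lists passed with the preset correlation and not with the estimated one. Of 33 G2/M genes 17 fell and 2 rose (22 and 2 adjusted over the list alone; camera adjusted p = 5.4e-04, and adjusted p = 0.41 with an estimated correlation). Of 54 cytosolic ribosomal protein genes 19 fell and 2 rose over all genes and also adjusted over the list alone (camera adjusted p = 0.0090, and adjusted p = 0.68 with an estimated correlation). RPL5 (-0.74, SE 0.06) and RPS20 (-0.60, SE 0.06) fell and RPL10A (0.61, SE 0.05) rose, all uncertain because processed pseudogenes can take such reads. Of 7 class II genes 5 rose and none fell over all genes and also adjusted over the list alone (camera adjusted p = 0.0090, and adjusted p = 0.23 with an estimated correlation). HLA-DRA reached 3.29 ± 0.249 CPM from 0.559 ± 0.0456 CPM. Of 17 class I genes 9 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.015, and adjusted p = 0.37 with an estimated correlation), with HLA-B lower (-1.07, SE 0.07). Their median was -0.48, and after correction for GC content and gene length the members in the first of the 3 parts of chromosome 6 had a median of -0.49 beside -0.30 for the other measured genes there and -0.13 for the 7 members elsewhere. The class I call was lost with a stricter filter (camera adjusted p = 0.059).

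Of 20 adhesion and integrin genes 9 rose and 2 fell over all genes and also adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.14 with an estimated correlation). With a stricter filter this call was lost (camera adjusted p = 0.058). THBS1 rose (3.28, SE 0.19), as did ITGB1 (1.05, SE 0.07), and ITGA6 fell (-0.93, SE 0.08). Of 22 p53 target genes 10 rose and 2 fell over all genes and also adjusted over the list alone (camera adjusted p = 0.024, and adjusted p = 0.14 with an estimated correlation). BTG2 rose (2.08, SE 0.09), and TP53INP1 (-2.45, SE 0.19) and FAS (-0.58, SE 0.12) fell. U937 cells are generally described as lacking functional p53. Of 30 glycolysis and hypoxia genes 11 fell and 4 rose over all genes and also adjusted over the list alone (camera adjusted p = 0.026, and adjusted p = 0.63 with an estimated correlation), with NDRG1 lower (-1.54, SE 0.12) and SLC2A1 higher (0.63, SE 0.12). Without replicate 2 of the libraries labelled shKDM6B that list did not pass (camera adjusted p = 0.065). Of 23 immediate early and heat shock genes 11 rose and 3 fell over all genes and also adjusted over the list alone (camera adjusted p = 0.026, and adjusted p = 0.37 with an estimated correlation). JUN (1.97, SE 0.09) and FOS (0.85, SE 0.10) rose. Without shControl replicate 1 this list did not pass either (camera adjusted p = 0.054), nor after the GC and length correction (adjusted p = 0.064), with which its median was 0.25 in place of 0.12. A stricter filter (camera adjusted p = 0.15) and the strand column (camera adjusted p = 0.051) ended its call too.

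Lists that did not pass in the libraries labelled shKDM6B still held strongly changed genes. After the GC and length correction 4 of them passed, with G1/S (camera adjusted p = 0.030) and MYC target genes (0.043) lower, and stress response (0.044) and primary granule genes (0.026, median -0.15) higher by the test. With an estimated correlation, and without the GC and length correction, none of the 4 passed (adjusted p = 0.23, 0.39, 0.41 and 0.41 in that order). LYZ and SRGN rose and CST7 fell (-1.13, SE 0.08) in the primary granule list, where 4 genes rose and 4 fell over all genes and also adjusted over the list alone. The median of that list was -0.27, its mean 0.02 and the direction of its test higher (camera adjusted p = 0.29). IL7R rose (2.85, SE 0.17) and PAX5 fell (-1.24, SE 0.13) among lymphocyte markers (median -0.09, mean 0.41, test higher, camera adjusted p = 0.59). NFE2 fell (-2.08, SE 0.18) and PPBP rose among erythroid and megakaryocyte markers (median -0.37, mean 0.51, test higher, camera adjusted p = 0.47). MYC fell from 177 ± 4.97 to 118 ± 5.41 CPM, and of the 27 MYC target and ribosome biogenesis genes 8 fell and 1 rose over all genes and also adjusted over the list alone (camera adjusted p = 0.13). Changes of MYC and of the other single genes in this group were not separated from those of their chromosome. The 375 measured genes of chromosome 8 had a median of -0.15 here after the GC and length correction (random gene sets -0.04 to 0.10). In the middle and last of its 3 parts the median was -0.41 and -0.21. HMGCS1, which encodes an early enzyme of cholesterol synthesis, fell (-1.26, SE 0.08), and INSIG1, which encodes a regulator of that pathway, rose (0.87, SE 0.07). Median, mean and test also differed in sign for the Fanconi anaemia, nucleotide excision, mismatch repair and stem and progenitor lists, none of which passed.

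**Figure D2:**
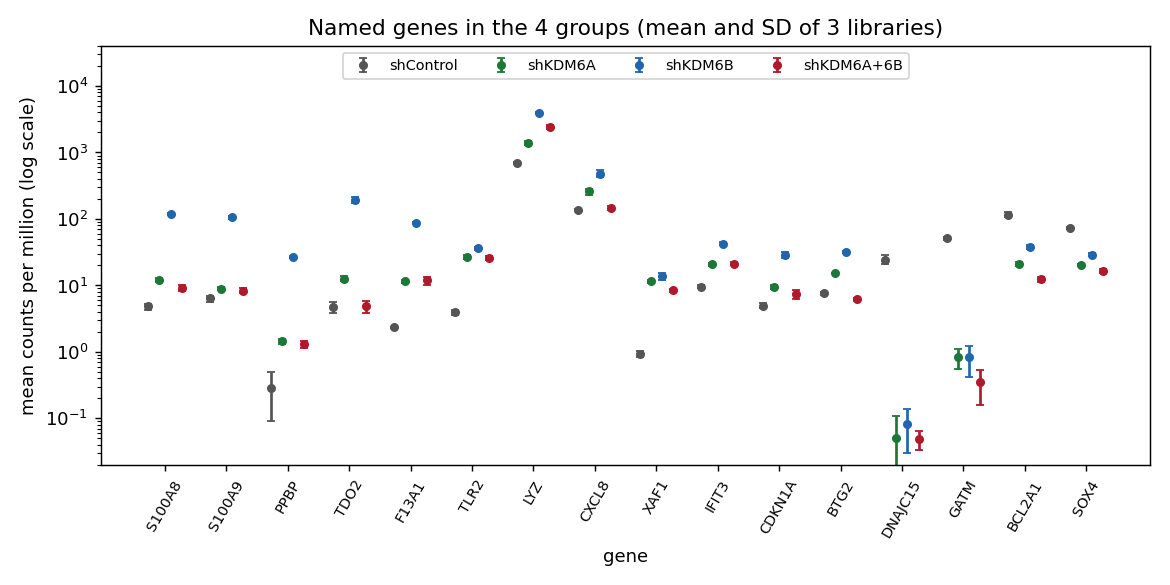
Mean CPM on a log scale (vertical axis) of 16 named genes (horizontal axis) in the 4 groups, with the SD of 3 libraries as bars. S100A8 reached 119 in the libraries labelled shKDM6B against 4.83 in shControl, while DNAJC15 and GATM were below 1 in all 3 knockdown groups.

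The comparison of the libraries labelled shKDM6A+6B with shControl addressed depletion of both demethylases. Like the other comparisons with shControl, it cannot tell depletion apart from another difference between the lines. Monocyte and macrophage genes and interferon-stimulated genes rose as groups, as did cytosolic ribosomal protein genes, by camera with a preset correlation. None of these 3 lists passed with an estimated correlation (adjusted p = 0.21, 0.21 and 0.77), and the ribosomal call was also lost with a stricter filter (adjusted p = 0.21), with the strand column (adjusted p = 0.062) and without shControl replicate 1 (adjusted p = 0.055). TLR2 rose from 3.98 ± 0.359 to 25.8 ± 1.67 CPM, LYZ from 695 ± 33.5 to 2426 ± 155 CPM and XAF1 from 0.933 ± 0.106 to 8.55 ± 0.442 CPM. BCL2A1 fell from 117 ± 9.20 to 12.4 ± 1.08 CPM. ASNS, the gene of asparagine synthetase, fell from 37.4 ± 1.89 to 4.85 ± 0.307 CPM. HMGCS1 fell from 1009 ± 67.6 to 295 ± 15.9 CPM. At an adjusted p below 0.05, 9323 genes changed, 4879 higher and 4444 lower, and 2977 of them changed at least 2-fold.

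The libraries labelled shKDM6A+6B also differed from shControl along GC content. The tenth of genes with the highest GC content had a median log2 fold change of 0.68 and the tenth with the lowest had -0.19, whereas in shKDM6A these medians were -0.07 and 0.0045. After correction for GC content and gene length, 7938 of the 9323 genes (85.1%) were called in the same direction and 14 in the opposite one. The balance of all calls turned with the correction, to 4929 higher and 5463 lower, and from 1520 higher and 1457 lower to 978 higher and 1575 lower among changes of at least 2-fold. In shKDM6A 99.2% and in the libraries labelled shKDM6B 98.4% of the called genes kept their direction and call.

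With the same limit and without the correction, the largest rises were those of GPR85 (log2 fold change 4.61, SE 0.19), PPP1R27, CSPG4, SERPINH1, SCARB1, KIF17, MCF2L and TIAM1 (3.45, SE 0.10). With the correction their values were 4.79, 3.57, 3.44, 3.52, 3.41, 2.78, 3.13 and 3.38 in that order. SCARB1, the gene of a lipoprotein receptor, went from 49.2 ± 8.96 to 656 ± 132 CPM, and TIAM1, the gene of a RAC1 activator, from 5.77 ± 0.649 to 63.2 ± 3.18 CPM. The largest falls were those of CTPS2, DNAJC15, GATM, UNC5C, MMP1, TMEM170B, PKP4 and YES1. CTPS2 had 1 read in the 3 libraries labelled shKDM6A+6B and 2159 reads in shControl, a 2047-fold ratio of CPM with a 95% counting interval of 367 to 80893. MMP1, the gene of an interstitial collagenase, went from 49.8 ± 4.64 to 0.522 ± 0.145 CPM, and YES1, the gene of a SRC family kinase, from 30.9 ± 2.09 to 0.599 ± 0.0673 CPM. By edgeR's quasi-likelihood test the adjusted p of these 16 genes was at most 1.4e-06.

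Of 36 monocyte and macrophage genes 18 rose and 4 fell over all genes and also adjusted over the list alone, with a median log2 fold change of 0.50 (camera adjusted p = 2.1e-05, and adjusted p = 0.21 with an estimated correlation). CD86, which encodes a costimulatory receptor, fell (-2.92, SE 0.26), as did ITGAL (-1.25, SE 0.15). Of 31 interferon-stimulated genes 20 rose and 3 fell (22 and 3 adjusted over the list alone), with a median of 1.01 (camera adjusted p = 3.7e-05, and adjusted p = 0.21 with an estimated correlation). IFI6 rose (1.31, SE 0.09) and PARP9 fell (-0.53, SE 0.10). Of 54 ribosomal protein genes 36 rose and 5 fell (36 and 6 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.0051, and adjusted p = 0.77 with an estimated correlation). RPL10A (0.97, SE 0.05, and 0.60 after the GC and length correction) and RPL11 (0.82, SE 0.08) rose and RPS20 (-0.49, SE 0.06) fell, with the same doubt over pseudogenes. With the correction for GC content and gene length the median of the ribosomal list was 0.26 and it passed (camera adjusted p = 0.019).

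Other lists did not pass in the libraries labelled shKDM6A+6B without the correction. With it 6 more passed, of which nucleotide excision repair (camera adjusted p = 0.0059) and primary granule genes (0.0096) were higher and anti-apoptotic BCL2 family and glycolysis genes (0.045 each) lower. With an estimated correlation, and without the GC and length correction, none of the 6 passed (adjusted p = 0.47, 0.47, 0.47 and 0.89 for these 4). Of 23 cholesterol synthesis genes 8 fell and 4 rose over all genes and also adjusted over the list alone (camera adjusted p = 0.17). ACAT2 fell (-1.10, SE 0.06) and FDFT1 rose (0.79, SE 0.05), and after the GC and length correction the list passed as lower (camera adjusted p = 0.0033, and adjusted p = 0.47 with an estimated correlation and no such correction). Of 28 stress response genes 18 rose and 4 fell (20 and 4 adjusted over the list alone; camera adjusted p = 0.11), with ATF4 higher (0.61, SE 0.07, and 0.21 after the correction) and ASNS lower. CDC20 (1.27, SE 0.16, and 0.81 after the correction) rose and MKI67 (-0.81, SE 0.07) fell among G2/M genes, of which 8 rose and 14 fell over all genes and also adjusted over the list alone (camera adjusted p = 0.24). Among 17 class I genes 3 rose and 6 fell over all genes and also adjusted over the list alone (camera adjusted p = 0.27), with HLA-B (-0.85, SE 0.07, and -1.35 after the correction) and B2M (-0.63, SE 0.08) lower. After the GC and length correction the class I list passed as lower (camera adjusted p = 0.0096, and adjusted p = 0.77 with an estimated correlation and no such correction), with 10 members in the first of the 3 parts of chromosome 6 at a median of -0.60, the other 185 genes there at -0.58 and the 7 members elsewhere at -0.21. The histone gene H1-5 rose (3.28, SE 0.27) and H3C4 fell (-5.05, SE 0.34), both uncertain because histone genes share sequence and their transcripts mostly lack a poly(A) tail. The 13 mitochondrially encoded genes held 6 that fell and none that rose over all genes and also adjusted over the list alone (camera adjusted p = 0.31).

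Among cell death and repair genes in the libraries labelled shKDM6A+6B, BCL2 (0.56, SE 0.06) and the pro-apoptotic gene BIK (1.97, SE 0.22) rose, and the death receptor gene FAS fell (-1.16, SE 0.12). FANCE (2.06, SE 0.15) and GTF2H3 (1.96, SE 0.07) rose, while the helicase gene WRN (-0.92, SE 0.09), the kinase gene ATM (-0.70, SE 0.09, and -0.45 after the GC and length correction) and FANCD2 (-0.74, SE 0.06) fell. Median, mean and test differed in sign for 8 lists, namely Polycomb, H3K4 methyltransferase, checkpoint, anti-apoptotic, NF-kappaB, adhesion, erythroid and lymphocyte genes, none of which passed without the correction.

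**Figure D3:**
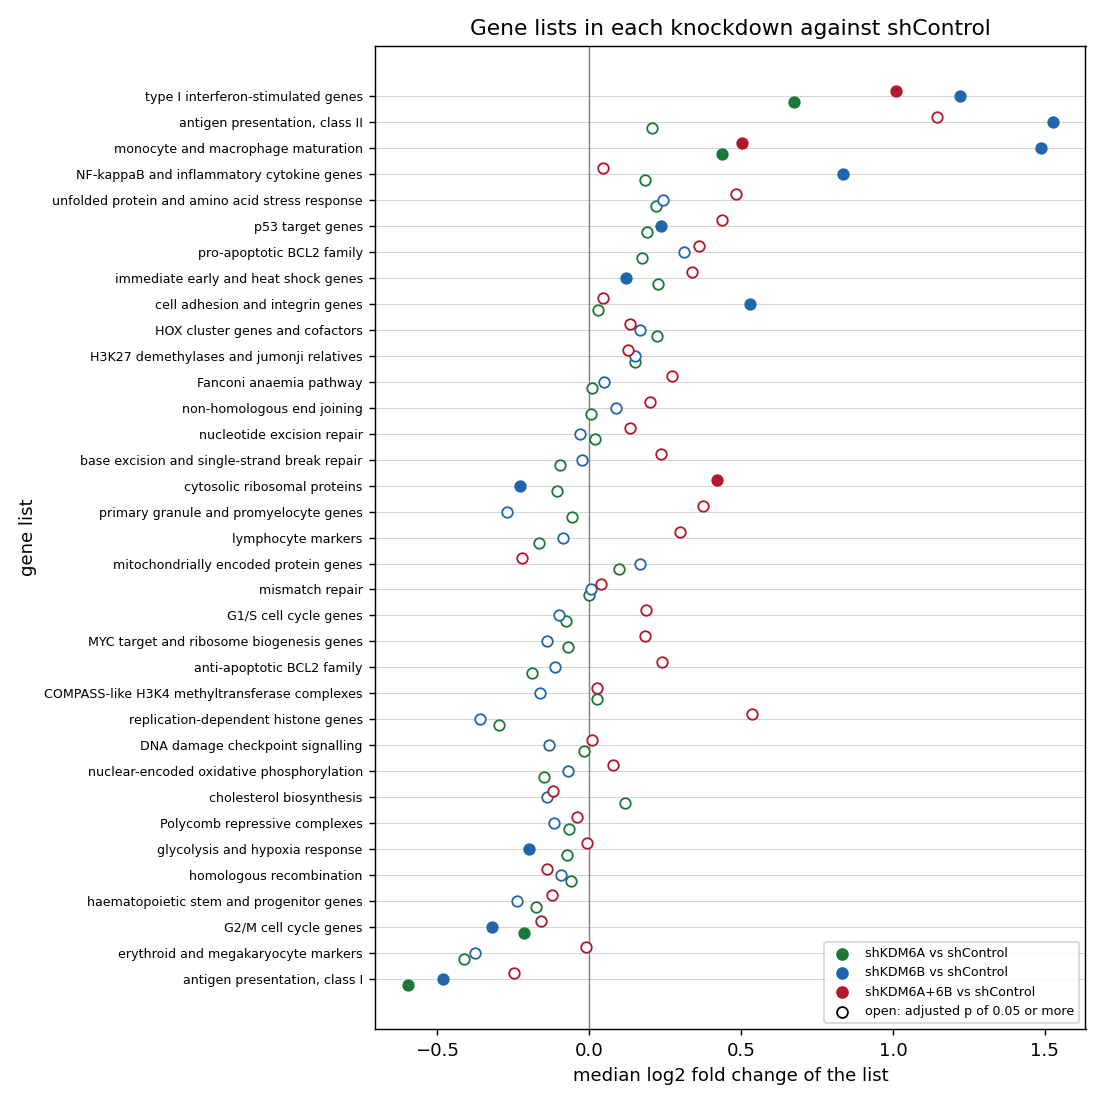
Median log2 fold change (horizontal axis) of each of 35 gene lists (vertical axis) in the 3 knockdown groups against shControl, with filled points for lists at a camera adjusted p below 0.05 with the preset correlation. Monocyte and macrophage genes had medians of 0.44, 1.49 and 0.50 in shKDM6A, shKDM6B and shKDM6A+6B.

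The 2 single knockdown groups shared many changed genes. In the same direction in both, 4647 genes were called, 2468 higher and 2179 lower, and 155 were called in opposite directions. CTPS2, DNAJC15, GATM and UNC5C fell and XAF1 rose in both. Independent lists of these sizes would share 690 higher and 624 lower genes. Both comparisons used the same 3 control libraries, and in 20 simulations of unchanged groups against those controls 0 genes were shared. Where nothing is changed almost no gene is called, so this 0 does not measure the overlap expected among changed genes. The correlation of the log2 fold changes was 0.80 across genes, which are not independent replicates, against a simulated mean of 0.49, and their covariance was 0.548 against a simulated 0.0291. The 3 controls could not be split into parts of 2 libraries each, so part of the excess may come from the shared controls. Counting all 3 knockdown groups, 1895 genes were higher and 1792 lower in each, and 131 were called in each with mixed direction.

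A direct test compared shKDM6A with the libraries labelled shKDM6B. These lines differed over whole chromosomes. Relative to all genes and to shControl, the median of chromosome 8 was 0.0030 in shKDM6A and -0.20 in shKDM6B. That of chromosome 18 was 0.03 and 0.20 (means of 3 libraries after the GC and length correction). The differences between these 2 groups are therefore not shown to follow from the hairpins. PPBP was at 1.45 ± 0.128 CPM in shKDM6A and 26.7 ± 0.938 CPM in the libraries labelled shKDM6B (log2 difference -4.20, SE 0.21). TMEM170B (-4.32, SE 0.22) and SEPTIN10 (-3.95, SE 0.14) were also lower in shKDM6A, SEPTIN10 at 1.47 ± 0.208 against 22.7 ± 1.46 CPM. ALDOC (1.58, SE 0.29), KIAA0825 (1.55, SE 0.14) and MAGED1 (1.51, SE 0.12) were higher in shKDM6A, MAGED1 at 18.04 ± 1.82 against 6.32 ± 0.749 CPM. KDM6A itself had a log2 difference of -0.87 (SE 0.08, edgeR adjusted p = 7.0e-06). In all, 3605 genes differed, 1285 higher and 2320 lower in shKDM6A. Without shKDM6A replicate 2 the count was 2357, and with the GC and length correction it was 6158.

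The libraries labelled shKDM6A+6B were compared with shKDM6A, to see what goes with the second hairpin. The lines also differed over whole chromosomes. Relative to all genes and to shControl, the median of chromosome 7 was -0.31 in shKDM6A+6B and 0.08 in shKDM6A. That of chromosome 8 was -0.26 and 0.0030 (means of 3 libraries after the GC and length correction). The differences below therefore cannot be credited to the second hairpin. SPP1, the gene of osteopontin, fell from 13.7 ± 2.74 CPM in shKDM6A to 0.369 ± 0.0952 CPM (36.9-fold), ASNS from 42.6 ± 0.940 to 4.85 ± 0.307 CPM, and CD109 from 39.3 ± 4.39 to 7.08 ± 0.693 CPM. SLPI, the gene of a secreted protease inhibitor, rose from 1.71 ± 0.148 to 9.21 ± 0.647 CPM, MAP3K6 from 4.08 ± 1.64 to 14.01 ± 3.28 CPM and MIIP from 3.95 ± 1.38 to 13.1 ± 3.31 CPM. With the GC and length correction the log2 values of MAP3K6 and MIIP went from 1.78 to 1.01 and from 1.73 to 0.83. KDM6A had a log2 difference of -0.34 (SE 0.09, edgeR adjusted p = 0.0090), a call lost without shKDM6A+6B replicate 2 (adjusted p = 0.067), and of -0.22 after the correction. KDM6B had a log2 difference of 0.16 (edgeR adjusted p = 0.55) and of -0.55 after the GC and length correction (adjusted p = 0.033).

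In this comparison 6444 genes differed, 3590 higher and 2854 lower, of which 69.4% kept their call and direction after the correction. With the correction 3688 were higher and 3559 lower, and changes of at least 2-fold went from 598 higher and 914 lower to 88 and 980. The count was 3971 without shKDM6A replicate 1 and 4213 without shKDM6A+6B replicate 3. The median of the tenth of genes with the highest GC content was 0.77 and that of the tenth with the lowest was -0.18.

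The libraries labelled shKDM6A+6B were also compared with those labelled shKDM6B. Here too the lines differed over whole chromosomes. Relative to all genes and to shControl, the median of chromosome 7 was -0.31 in shKDM6A+6B and 0.04 in shKDM6B. That of chromosome 18 was 0.02 and 0.20 (means of 3 libraries after the GC and length correction). The differences between these 2 groups therefore cannot be credited to the hairpin against KDM6A. TDO2 fell from 194 ± 18.03 to 4.85 ± 0.945 CPM (40.1-fold), MMP1 from 21.7 ± 1.93 to 0.522 ± 0.145 CPM and SEPTIN10 from 22.7 ± 1.46 to 0.498 ± 0.112 CPM. CSPG4 rose from 2.31 ± 0.682 to 13.1 ± 2.75 CPM, PPP1R27 from 11.2 ± 4.81 to 53.02 ± 14.9 CPM, and ELANE, the gene of neutrophil elastase, from 5.65 ± 2.71 to 25.4 ± 13.3 CPM. The log2 differences of CSPG4 and ELANE were 2.50 (SE 0.29) and 2.17 (SE 0.45), and 1.64 and 1.02 after the GC and length correction. KDM6A had a log2 difference of -1.21 (SE 0.09, edgeR adjusted p = 2.2e-07), and KDM6B had a log2 difference of 0.38 (edgeR adjusted p = 0.13). Without replicate 1 of the libraries labelled shKDM6A+6B the KDM6B value was 0.56 and passed (adjusted p = 0.031), and with the GC and length correction it was -0.44 (adjusted p = 0.084). In all, 7506 genes differed, 3847 higher and 3659 lower, and 70.4% kept their call and direction after the correction. With the correction the balance turned to 3328 higher and 4549 lower, and changes of at least 2-fold went from 1004 higher and 969 lower to 182 and 1102.

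The interaction tested whether the double knockdown departed from the sum of the single ones on the log scale. It is the double knockdown minus both single ones plus shControl, so a change common to all 3 knockdown groups, or a control line that stands apart, gives a value of opposite sign by construction. Of the 3687 genes changed alike in all 3 groups, 2554 had an interaction of opposite sign and 19 one of the same sign. TDO2 was at 194 ± 18.03 CPM in the libraries labelled shKDM6B, 12.7 ± 1.07 CPM in shKDM6A and 4.85 ± 0.945 CPM in those labelled shKDM6A+6B, an interaction of -6.75 (SE 0.21, edgeR adjusted p = 7.9e-11). ATP6V0D2 (-7.72, SE 0.22) and PPBP (-6.66, SE 0.36) also had negative values. SLPI had a positive interaction (3.74, SE 0.23), at 12.4 ± 2.25 CPM in shControl, 1.71 ± 0.148 in shKDM6A, 4.98 ± 0.668 in shKDM6B and 9.21 ± 0.647 in shKDM6A+6B. DNAJC15 (8.10, SE 1.33) and GATM (4.75, SE 0.59) also had positive values, but both were below 1 CPM in all 3 knockdown groups, so that the sum of 2 large falls lies under what the counts can show. KDM6A had an interaction of -0.64 (SE 0.12, edgeR adjusted p = 9.1e-04). In all, 7378 genes had an interaction, 3666 positive and 3712 negative, and 82.2% kept their call and sign after the GC and length correction, with which 3708 were positive and 4731 negative. Values of at least 2-fold went from 1549 positive and 1837 negative to 612 and 2094.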

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

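All tests of explanations in this part were chosen only after the results were seen. The interaction of the knockdowns held 7378 genes, more than any other of 100 groupings of the 12 libraries (highest other 1855), which excludes chance only for libraries that do not differ between groups at all. Such groupings mix the groups, so they do not test for an interaction beside real differences. A change common to all 3 knockdown groups also gives an interaction of opposite sign by construction, as in 2554 of the 3687 genes changed alike in all 3. The effect of the shKDM6B label on KDM6A RNA differed with and without shKDM6A (interaction -0.64). The same test gave 8.10 for DNAJC15, 4.75 for GATM, 3.74 for SLPI, -7.72 for ATP6V0D2, -6.75 for TDO2 and -6.66 for PPBP. Outside the counts used for the tests, the share of reads without an alignment was highest in shKDM6A (20.4% ± 1.87, shControl 13.9% ± 1.10). The share of reads aligned to several places was highest in shKDM6A+6B (4.73% ± 0.338, shControl 3.60% ± 0.0993).

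KDM6B RNA was not detectably lower in the libraries labelled shKDM6B, while KDM6A RNA fell in the groups named for it. Too few reads to see a halving was argued against, because the lower 95% bound was -0.61 on the log2 scale. A GC and length trend hiding such a drop was argued against too, since the bound after correction was -0.42. In the libraries labelled shKDM6A+6B a hidden drop stays open: KDM6B went from 0.19 to -0.44 with the correction (95% interval -0.85 to -0.03, adjusted p = 0.0633), and against shKDM6A from 0.16 to -0.55 (95% interval -0.97 to -0.14, adjusted p = 0.033). A smaller drop in RNA, a loss of protein alone, a weak hairpin and a wrong label also stay open and were not tested.

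The changes shared by the 3 knockdown groups were the second pattern. After removal of a GC and length trend the single knockdowns shared 6392 genes. Calls rose in both comparisons with that correction, so this count does not decide. The covariance of their fold changes was 0.543 after it and 0.548 before, with a correlation of 0.80 in both, which argues against that trend. Chance values of the shared controls within the spread between replicates were argued against too (covariance 0.548, simulated 0.0291). A larger deviation common to the control libraries was not simulated. Lower KDM6A RNA as the whole cause was argued against, since 78.0% of the 4728 genes changed alike in shKDM6A and shKDM6A+6B also changed so in shKDM6B, where KDM6A RNA was not lower (at most 0.0208% in 20 simulations with shKDM6B unchanged and the controls shared). The 3687 genes on which shControl differed in 1 direction from each other group are the shared changes themselves, so they say nothing of their origin. A difference of the control line and an effect common to the knockdowns cannot be told apart, since no second control line was analysed here.

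The third pattern was that genes of whole chromosome segments moved together. The 104 measured genes of chromosome 21 had median log2 fold changes of -0.47, -0.43 and -0.42 in shKDM6A, shKDM6B and shKDM6A+6B after the GC and length correction, and -0.47 lay below the range of random gene sets, which argues against a GC trend. A few strongly changed genes were argued against, since at least 86.5% of these genes were lower in each knockdown group. A copy number difference between the control and the knockdown lines is a candidate explanation: each of 3 equal parts of the chromosome lay below random sets (highest -0.28), and class I genes in the first of 3 such parts of chromosome 6 differed from their neighbours there by -0.034 in shKDM6A, -0.189 in shKDM6B and -0.0164 in shKDM6A+6B, so that the class I list in shKDM6B is less close to its neighbours. No DNA was analysed here, so copy number itself was not measured, and regulation of whole domains stays open.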

How the results depend on the processing

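The GC and length correction was chosen after seeing the data; the other alternatives were planned, and where a value moved the cause was not tested unless stated. With a 2-fold minimum, which by construction lowers counts, 2004 genes were called in shKDM6A, 2258 in shKDM6B and 2977 in shKDM6A+6B against shControl, 770 between the single knockdowns, 1512 and 1973 for shKDM6A+6B against shKDM6A and shKDM6B, and 3386 for the interaction. The GC and length correction gave 6158 genes between the single knockdowns (3605 without it), with 2340 higher and 3818 lower (1285 and 2320 without it). No other planned setting with all libraries moved a total by over 1.5 times, but the stricter filter, which tests fewer genes, lowered the higher calls from 3359 to 2162 in shKDM6A and from 4879 to 3133 in shKDM6A+6B. Leaving out 1 library gave 2357 (without shKDM6A replicate 2) to 3796 genes between the single knockdowns, and 3971 (without shKDM6A replicate 1; 4213 without shKDM6A+6B replicate 3) to 7149 for shKDM6A+6B against shKDM6A. Higher calls between the single knockdowns fell from 1285 to 637 without shKDM6A replicate 2 and 818 without shKDM6B replicate 3. For shKDM6A+6B against shKDM6A the higher calls were 1866 without shKDM6A replicate 1 and 2080 without shKDM6A+6B replicate 3 in place of 3590, and the lower calls 1804 in place of 2854 without shKDM6A+6B replicate 2. Against shKDM6B the higher calls were 2563 in place of 3847 without shKDM6B replicate 2.

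KDM6B values against shControl changed sign, none being called: -0.021 in shKDM6A with no filter (-0.098 to 0.085 with 1 library left out), 0.0047 in shKDM6B and -0.44 in shKDM6A+6B after the correction. With 1 library left out, KDM6B in shKDM6B ranged from -0.33 (without shControl replicate 1) to -0.13, and in shKDM6A+6B it was 0.064 without shControl replicate 1, 0.047 without its replicate 2 and 0.34 without its replicate 1, against -0.19 and 0.19 with all libraries. Corrected values were -0.55 against shKDM6A, which passed, -0.44 against shKDM6B and -0.56 for the interaction. KDM6A in shKDM6B ranged from 0.25 to 0.39 with 1 library left out, and without shControl replicate 2 it was 0.28 and not called.

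Counts of lists depended on the test. In shKDM6A, shKDM6B and shKDM6A+6B they were 4, 11 and 3 as reported, 15, 18 and 15 with no filter, 0, 3 and 0 with an estimated correlation, and 24, 25 and 21 with fry, which tests each list by itself. The stricter filter gave 7 in shKDM6B, and the correction gave 6, 14 and 9. With 1 library left out they ranged from 4 to 7 in shKDM6A (7 without its replicate 3) and 2 to 5 in shKDM6A+6B (5 without its replicate 1 or 3). The stricter filter also ended the calls of class I (adjusted p = 0.059), adhesion (0.058) and immediate early genes (0.15) in shKDM6B, of G2/M genes in shKDM6A (0.11) and of ribosomal genes in shKDM6A+6B (0.21). The strand column ended those of the G2/M genes (0.080), the ribosomal genes (0.062) and the immediate early genes (0.051), and the correction that of the immediate early genes (0.064), although their median rose from 0.12 to 0.25.

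With the replicate number as a replicate block, 6386, 7137 and 9115 genes were called against shControl. Of 18 same-numbered pairs 6 correlated above 0.1 (-0.44 to 0.34), so the numbers were not taken as pairs. All 6 were of number 1 or 3 among shControl, shKDM6A and shKDM6A+6B, as were all 12 of 36 comparisons that were best with the own number, and none involved shKDM6B. In those 3 groups the GC content trend also rose with the number. The median of the highest-GC genes minus that of the lowest-GC genes was -0.52, -0.0097 and 0.14 in shControl replicates 1 to 3. It was -0.75, -0.24 and 0.26 in shKDM6A, 0.32, 0.83 and 1.02 in shKDM6A+6B, and 0.18, -0.75 and -0.47 in shKDM6B. Replicate 2 of shKDM6B, lowest there, correlated with number 1 of the other groups (0.27, 0.35 and 0.28). The correlations therefore cannot tell something shared by number, which the labels do not state, from this trend.

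With 6 libraries only 10 splits exist, too few to exclude chance; the real counts were 5954, 6891 and 9437 genes against shControl, 2524 between the single knockdowns, and 5840 and 7024 for shKDM6A+6B against each, with 0 in every other split. For lists, 8, 3 and 7 of the 10 splits gave as many (highest others 10, 12 and 7). The 4647 genes shared by the single knockdowns exceeded all others of 100 groupings (highest 303), which again excludes chance only for groups with no difference at all. Depth limits low genes such as KDM6B, for which a log2 drop within the 95% interval (lower bound -0.61 in shKDM6B) could be missed.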

Other observations

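The list tests between knockdown groups in this part were added after seeing the data. Monocyte and macrophage genes were lower in shKDM6A than in the libraries labelled shKDM6B, with 25 of 36 lower and 2 higher (28 and 3 adjusted over the list alone; median -0.996, camera adjusted p = 2.8e-48, and adjusted p = 3.1e-04 with an estimated correlation). In the libraries labelled shKDM6A+6B they were lower than in those labelled shKDM6B too, with 24 lower and 3 higher (26 and 4 adjusted over the list alone; median -0.94, camera adjusted p = 3.0e-26, and adjusted p = 0.0020 with an estimated correlation). The interaction was negative for 28 and positive for 2 of these 36 genes over all genes and also adjusted over the list alone (median -1.63, camera adjusted p = 2.5e-29, and adjusted p = 0.0012 with an estimated correlation). The monocyte and interferon lists rose in all 3 knockdown groups against shControl with the preset correlation. With an estimated correlation neither passed in shKDM6A (camera adjusted p = 0.18 each) or in shKDM6A+6B (0.21 each). A rise common to all 3, or a control line that stands apart, gives a negative interaction by construction. Interferon-stimulated genes had a median interaction of -1.07 (23 negative and 3 positive of 31, 23 and 4 adjusted over the list alone; camera adjusted p = 1.9e-14, and adjusted p = 0.014 with an estimated correlation).

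Ribosomal, MYC target, granule and cholesterol synthesis genes were compared between the libraries labelled shKDM6A+6B and shKDM6A. Counts and adjusted p values here come from the fit without the GC and length correction. These groups differed along GC content (median 0.77 in the tenth of genes with the highest GC content, -0.18 in the lowest). They also differed over chromosomes 7 and 8, so the list differences cannot be credited to the second hairpin. Against shKDM6A, the libraries labelled shKDM6A+6B had 49 of 54 ribosomal protein genes higher and none lower (49 and 1 adjusted over the list alone), with a median of 0.50 and of 0.34 after the GC and length correction (camera adjusted p = 5.6e-17, and adjusted p = 0.26 with an estimated correlation). MYC target and ribosome biogenesis genes had 14 of 27 higher and 1 lower (15 and 1 adjusted over the list alone; median 0.21, camera adjusted p = 1.2e-04, and adjusted p = 0.048 with an estimated correlation). Primary granule genes had 11 of 15 higher and none lower (12 and none adjusted over the list alone; median 0.64 and 0.32 after the correction, camera adjusted p = 2.1e-07, and adjusted p = 0.010 with an estimated correlation). Cholesterol synthesis genes had 11 of 23 lower and 2 higher over all genes and also adjusted over the list alone (median -0.23 and -0.46 after the correction, camera adjusted p = 3.9e-08, and adjusted p = 0.010 with an estimated correlation).

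Single libraries differed in GC content trend within their groups. The difference between the median of the tenth of genes with the highest GC content and that of the tenth with the lowest ran from -0.75 in shKDM6A replicate 1 to 1.02 in shKDM6A+6B replicate 3, and in shControl from -0.52 to 0.14. The common dispersion was 0.0120 without and 0.0029 with the GC and length correction. The number of genes with at least 1 read was 34793 ± 401 in shKDM6A and 34131 ± 434 in shKDM6B, against 30108 ± 443 in shControl and 30333 ± 566 in shKDM6A+6B (mean ± SD, n = 3).

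Beyond chromosome 21, the 388 measured genes in the first of 3 equal parts of chromosome 1 by gene order had median log2 fold changes of 0.32, 0.41 and 0.52 in shKDM6A, shKDM6B and shKDM6A+6B after the GC and length correction. In the same order the medians were -0.16, -0.13 and -0.11 for chromosome 5 and -0.24, -0.12 and -0.18 for chromosome 15. They were 0.10, 0.21 and 0.19 for chromosome 12. All of these whole-chromosome medians lay outside the range of random gene sets. Those of chromosomes 9, 10 and 14 lay within it in all 3 groups. The median of chromosome 7 relative to all genes was -0.31 ± 0.0139 in shKDM6A+6B and 0.08 ± 0.0110 in shKDM6A (mean ± SD of 3 libraries, relative to shControl). Chromosome 18 was at 0.20 ± 0.0240 in shKDM6B and at 0.03 ± 0.0283 in shKDM6A. Chromosome 8 was at -0.20 ± 0.0150 in shKDM6B and at 0.0030 ± 0.0301 in shKDM6A. Across 10976 pairs of neighbouring genes, which are not independent replicates, Spearman's correlation of the corrected changes was 0.33, 0.29 and 0.31 in shKDM6A, shKDM6B and shKDM6A+6B, and at most 0.0340 in 1000 shuffles of gene order.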
